A study of Mus musculus with 3 samples.

How the data were processed

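RNA of 3 normal thymi was profiled by RNA-seq. Per the labels, the mice were C57BL/6 with floxed Cic alleles and had received tamoxifen, nucleic acid was isolated with a column kit for DNA and RNA, and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps strand. The deposited values are raw read counts per gene, 1 library each, in 3 columns: reads of either strand, reads on the gene's strand and reads on the reverse strand. STAR 2.5.3a, DESeq2 without a version, and the build GRCm38 are named in the submitters' processing notes. The layout is that of STAR's own gene counting, which counts only uniquely mapped reads. The annotation release, trimming and any filter are not given in the sources used here. The counts are whole numbers with different totals per library, so they carry no normalisation.

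The reverse-strand column was used, since dUTP kits place a transcript's own reads there, and its total was the higher of the stranded columns in all 3 libraries. Of all reads, 67.7%, 69.1% and 66.4% in thymus 1, 2 and 3 were assigned to genes. Multimapping reads made up 14.4%, 14.0% and 15.5%, and reads on no annotated exon of the counted strand 14.4%, 13.5% and 14.6%. Unmapped reads made up 2.38%, 2.31% and 2.43%, and ambiguous reads 1.06%, 1.10% and 1.05%. The 4 summary lines that hold those classes entered no library size or test. Because multimapping reads are dropped, genes with near-identical copies are counted low, mt-Co2 among them, which shares 100% of its 50-base stretches with another transcript. Of 52636 gene identifiers, 52489 matched GENCODE release M21 on GRCm38 by identifier without version, and 147 did not. Symbols, coordinates (1-based), exon lengths and transcript GC content come from that release.

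Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR filter on low counts (minimum 10, total 15) left 16548 genes. TMM factors were 1.00, 1.03 and 0.971. The group has 1 condition, so no contrast between groups exists. The test of variability fitted an intercept only with edgeR's robust quasi-likelihood, divided each gene's quasi-dispersion by the trended prior and referred it to the F distribution with the residual and 5.24 prior degrees of freedom, one-sided, with Benjamini-Hochberg adjustment at 0.05. Variation beyond counting noise was tested with edgeR's goodness of fit at a dispersion of 0. At an unadjusted p under 0.05 there were 731 genes in the first test, where 827.4 would by chance. P-values measure only the spread between these samples, which may be technical in part, as the labels name no animal per library.

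A set of 29 gene lists with 294 distinct genes, all found, covered capicua with its partners and targets, thymocyte stages, other cell types, and stress, hormone, clock and cell cycle genes. The samples, tests, lists, alternatives and the rule for naming genes were set before the data were examined. The rule took Cic, its partners and all its listed targets, the 4 most abundant members of each stage, T cell receptor and leukaemia list and any of their members below 1 CPM in all libraries, the 3 most abundant of every other list, the 20 most abundant genes not encoded by mitochondria, up to 25 variable genes of at least 1 CPM that are not predicted genes, and the 8 genes with the most opposite-strand reads. Genes named outside that rule, namely Ccl22, mt-Co2, Mroh2a, Tpm3, the partners of opposite-strand genes and those so described, were chosen after their values were seen. Some genes that the rule takes are not reported here.

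For each list and library the median deviation of log2 CPM (prior count 2) from the gene mean was compared with 10000 random lists of the same size drawn within 20 expression bins. Sharing between transcripts was measured as the percent of a gene's 50-base stretches found in transcripts of other genes. The trend with GC content was removed per library by a lowess curve with span 0.3, an addition made after the data were seen, as were a joint correction for GC content and exon length and levels per kilobase of exon.

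The variability test was checked on counts simulated for 16548 genes from the real means and library sizes, with 200 genes changed in 1 library. It recovered 3 of 67 at 2-fold, 40 of 67 at 4-fold and 66 of 66 at 16-fold, with 10 false calls among 119. A list was raised in 1 simulated library to an expected deviation from the gene mean of 0.33 in log2. It was recovered at 0.36, above all random lists. Alternatives covered the unstranded column, DESeq2 size factors, library totals, no filter or a mean of at least 5 CPM, a prior that is not robust, goodness of fit and DESeq2 dispersion outliers in place of the quasi-likelihood test, libraries without mitochondrial genes, each library left out in turn, and the additions above. Binomial intervals and the 3-count limit cover counting error only, since reads carry no molecular identifiers. Groups of 3 are too small for a test of outlying samples.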

Results

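The study set T cell lymphomas that lack Cic against normal thymus of littermate controls. Cic encodes capicua, an HMG-box repressor of genes induced by receptor tyrosine kinase signalling. The thymus is the organ in which T cells mature. The data described here are RNA-seq gene counts of 3 normal thymi from tamoxifen-treated C57BL/6 mice with floxed Cic alleles, the control group. The lymphomas are not analysed here, so what follows is the control side of that comparison: its levels and its replicate error. The libraries, called thymus 1, 2 and 3 after the replicate numbers of the labels, held 44932368, 41345114 and 38265510 reads. Of these, 30414788, 28587087 and 25408442 were assigned to genes on the transcribed strand. Levels are CPM, read counts scaled to a common library size by TMM, and errors are SDs over the 3 libraries. A gene at 3 counts lies between 0.0986 and 0.122 CPM, which limits what could be detected in 1 library. A total of 14178 genes reached 1 CPM in every library, 12778 of them protein-coding.

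The first question was how strongly normal thymus expresses Cic and the genes it represses. Cic (chromosome 7, 25267704 to 25294159, plus strand, GRCm38) was expressed at 264 ± 6.24 CPM (SD, n = 3), with 259, 271 and 262 CPM in thymus 1, 2 and 3. Its coefficient of variation was 2.36%, against a median of 9.06% over all genes tested. Both ATXN1-family partners of capicua were expressed, Atxn1 at 31.3 ± 2.68 and Atxn1l at 75.1 ± 0.291 CPM. The 16 genes listed as capicua targets spanned a wide range. The ETS factor genes, the best known targets, were low: Etv4 at 0.398 ± 0.146, Etv1 at 2.03 ± 0.109 and Etv5 at 5.06 ± 0.658 CPM.

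Feedback inhibitors of the MAP kinase pathway differed in level. The phosphatase gene Dusp6 stood at 45.1 ± 2.64 and Dusp4 at 13.5 ± 3.53 CPM. Spred1 and Spred2 were at 54.7 ± 1.95 and 36.6 ± 3.58 CPM, and Spred3 at 4.08 ± 0.519. Of the Sprouty genes, Spry1 was at 6.07 ± 0.707, Spry2 at 5.82 ± 0.0745 and Spry4 at 1.30 ± 0.503 CPM. The cyclin genes Ccnd2 and Ccnd1 were at 132 ± 6.04 and 26.1 ± 2.41 CPM. Shc4, an adaptor gene, was at 1.76 ± 0.352 CPM. Etv4, Shc3 and Fosl1 lay below 1 CPM in all 3 libraries. Fosl1 had 3, 0 and 3 counts, at or below the 3-count limit, and Shc3 had 3, 9 and 2. Of the 13 target genes with enough counts to test, 0 were more variable between thymi than other genes of like abundance (edgeR quasi-likelihood test, Benjamini-Hochberg threshold 0.05), and 0 when adjusted over the list alone. By the same test 1 of them, Dusp4, had an unadjusted p under 0.05, and the DESeq2 dispersion check and the negative binomial goodness of fit each called 0.

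The second question was which stages of T cell development the RNA represents. Rag1 encodes a subunit of the recombinase that assembles antigen receptor genes. It had the most reads of any gene not encoded by mitochondria, at 4075 ± 169 CPM (SD, n = 3), not scaled by transcript length. Tcf7 and Satb1, transcription factor genes of the T lineage, followed among the double-positive genes at 2631 ± 180 and 1925 ± 126 CPM, and the co-receptor gene Cd8a at 1829.7 ± 38.6. All 14 double-positive genes exceeded 10 CPM in every library and 12 exceeded 100 CPM. Of the 10 genes of the T cell receptor complex, all exceeded 100 CPM, led by Trbc2 at 2451 ± 474, the kinase gene Lck at 1984 ± 120, Trbc1 at 1804 ± 243 and the adaptor gene Lat at 989 ± 55.3. Trbc1 and Trbc2 share 40.54% and 44.01% of their 50-base stretches with other transcripts, so reads that map equally well to both were not counted.

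Genes of early progenitors and double-negative cells were far lower. Their list median was 9.35 ± 1.42 CPM against 917 ± 28.3 for the double-positive list, a ratio of 99.9 ± 18.2 within libraries. Notch3 (55.6 ± 9.87), Il2ra, the interleukin-2 receptor alpha chain (53.7 ± 8.90), Dtx1 (17.4 ± 2.04) and Spi1 (15.1 ± 2.93) led that list. Mature single-positive genes lay between, with a list median of 48.9 ± 6.78 CPM and a ratio of 19.1 ± 3.14. They included Cd5 at 185 ± 12.1, Il7r at 82.3 ± 10.5 and Ccr7 at 78.6 ± 16.4 CPM. Longer transcripts gather more reads. Per kilobase of exon, a scale added after the data were seen, the ratios were 54.8 ± 11.4 and 13.3 ± 1.54. The double-positive median was 1.45 ± 0.0532 times that of the T cell receptor complex in CPM. Per kilobase it was 0.485 ± 0.0198 times, so the order of these lists depends on the scale. With 3 libraries an exact two-sided sign-flip test cannot go below p = 0.25, so the ratios stand as description.

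Of 15 genes tied to Notch signalling and T cell leukaemia 5 were at 10 CPM or more in every library, 7 below 1 CPM in every library and 3 in neither set. Ikzf1, Bcl11b and Notch1 were at 651 ± 60.1, 479.6 ± 22.2 and 199 ± 18.2 CPM. The homeobox genes Tlx1, Tlx3, Hoxa9 and Hoxa10 and the genes Tal1 and Lmo1, which are switched on in subtypes of this leukaemia, and the Notch target Hes5 were low. Tlx3 had 1, 0 and 0 counts, Hoxa10 0, 2 and 0, and Tlx1 1, 6 and 0. Hoxa9 stood at 0.209 ± 0.104, Hes5 at 0.531 ± 0.234, Tal1 at 0.604 ± 0.173 and Lmo1 at 0.6501 ± 0.0870 CPM, all 7 below 1 CPM in every library.

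**Figure D1:**
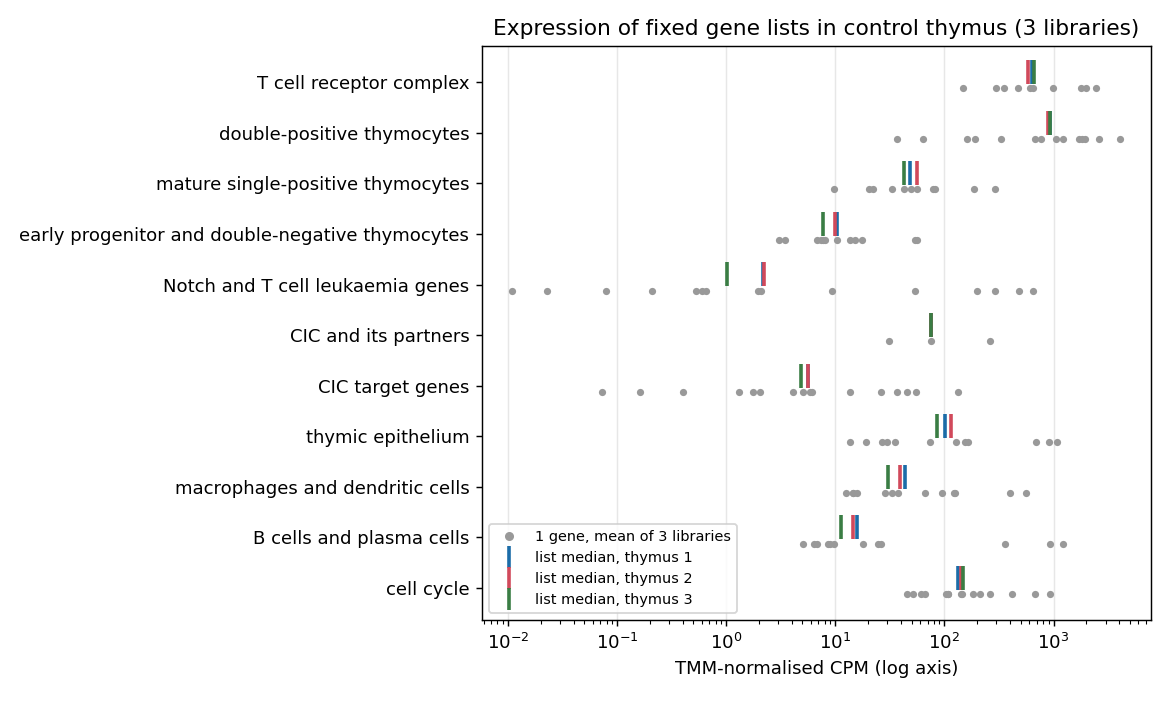
Expression of gene lists in the 3 control thymi. The horizontal log axis gives TMM-normalised CPM, grey points are single genes as the mean of 3 libraries, and coloured ticks are the list median in each thymus. Double-positive and T cell receptor genes lie highest, with mean list medians of 917 and 632 CPM, and capicua target genes lie near 5.37 CPM. Per kilobase of exon, not shown, the T cell receptor median lies above the double-positive median.

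Other cell types of the organ were visible at lower levels. The thymic epithelium list was led by Ctsl (1069.5 ± 93.1 CPM), the protease gene Prss16 (906 ± 51.8) and the chemokine gene Ccl25 (684 ± 62.6). All 12 genes of that list exceeded 10 CPM in every library. All 13 macrophage and dendritic cell genes also exceeded 10 CPM, led by Lyz2 (556 ± 114), Cst3 (399.7 ± 5.20) and C1qc (125 ± 5.36). B cell and plasma cell transcripts were led by the immunoglobulin genes Ighm (1215 ± 15.3) and Igkc (922 ± 41.4) and by Jchain (355 ± 106), while the list median was 13.8 ± 2.35 CPM. Among innate-like and gamma-delta T cell genes, Trdc was at 129 ± 4.60, Gzma at 95.5 ± 23.2 and Tcrg-C2 at 56.3 ± 7.68 CPM. Regulatory T cell genes were led by Ikzf2 (147 ± 15.9), Il2rb (33.0 ± 5.15) and Tnfrsf18 (29.8 ± 1.01). Ikzf2 and Il2rb are not restricted to regulatory T cells.

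Stroma and neighbouring tissue gave smaller signals. Endothelial genes were led by Pecam1 at 103 ± 10.6 CPM, and the list median was 4.08 ± 0.624. Dcn (98.3 ± 16.7), Col3a1 (24.6 ± 2.62) and Mgp (20.7 ± 0.915) marked mesenchyme. Car3 (72.7 ± 19.4), Adipoq (21.9 ± 4.67) and Cfd (16.4 ± 4.22) marked fat. Pth, which encodes parathyroid hormone, was at 51.2 ± 22.2 CPM, with 75.4, 31.8 and 46.3 CPM in thymus 1, 2 and 3. The muscle gene Mylpf was at 30.02 ± 1.59 CPM, and 5 of the 8 muscle genes were below 1 CPM in every library. The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were at 372 ± 75.2, 164 ± 14.0 and 119 ± 10.1 CPM. Proliferation genes were high, with Mki67 at 930.2 ± 106, Top2a at 681 ± 75.8 and Pcna at 412 ± 85.4 CPM.

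The third question was how far normal thymi differ from each other, the error against which a tumour would be judged. Pearson correlations of log2 CPM across 16548 genes, which are not independent replicates, were 0.994, 0.994 and 0.991 for thymus 1 with 2, 1 with 3 and 2 with 3. The biological coefficient of variation was 10.9%. Still, 7188 genes (43.4%) varied by more than counting noise (Poisson goodness of fit, edgeR, Benjamini-Hochberg 0.05). This count was 6579 without thymus 1, 4348 without thymus 2 and 3768 without thymus 3.

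Of the 16548 genes 10 varied more than the trend for their abundance (edgeR quasi-likelihood, Benjamini-Hochberg 0.05, one-sided), and 5 of them were erythroid. The count was 122 by negative binomial goodness of fit, 81 by DESeq2 dispersion outliers, 20 by edgeR with library totals and 285 by edgeR with no filter. Hbb-bs, a beta globin gene, was at 663, 29.7 and 146 CPM in thymus 1, 2 and 3 (edgeR adjusted p = 0.00625). Hbb-bt, Hba-a1 and Hba-a2 had the same order, with the highest value 17.9, 23.2 and 22.4 times the lowest. Alas2, the erythroid enzyme of haem synthesis, had 863, 44 and 144 counts, with the highest level 18.9 times the lowest (edgeR adjusted p = 0.0387). The alpha and the beta globin genes share 53.2% to 89.3% of their 50-base stretches with other transcripts, so the level of each single gene is uncertain.

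The other 5 variable genes stood apart in 1 thymus each. Slc15a2, a peptide transporter gene (chromosome 16, 36750177 to 36784962), was at 1.91 CPM in thymus 1 against 139.6 and 213 CPM in thymus 2 and 3 (edgeR adjusted p = 0.00625). Dmbt1 (chromosome 7, 131032053 to 131121630) was at 36.2 CPM in thymus 1 against 0.682 and 0.406. Gdpd3 (chromosome 7, 126766334 to 126775649) was at 54.1 CPM in thymus 1 against 4.30 and 5.19 (edgeR adjusted p = 0.0106). Tpm3-rs7 (chromosome 14, 113314608 to 113316754), annotated as a relative of the tropomyosin gene Tpm3, was at 38.7 CPM in thymus 2 against 1.02 and 0.446. It shares 69.5% of its 50-base stretches with other transcripts, mainly of Tpm3. The immunoglobulin gene Igkv12-89 was at 28.3, 2.05 and 4.54 CPM (edgeR adjusted p = 0.0399).

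Part of these calls rest on 1 library. Without thymus 1, Slc15a2, Dmbt1, Gdpd3, Igkv12-89 and Alas2 were no longer called, and without thymus 2 Tpm3-rs7 was not, while the 4 globin genes were called with any 1 library left out. The number of called genes was 25 without thymus 1, 23 without thymus 2 and 137 without thymus 3, and 5, 9 and 10 of these were among the 10. In simulated data with the same depth the test recovered 4.48% of genes changed 2-fold in 1 library, 59.7% of those changed 4-fold and all 66 of those changed 16-fold.

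**Figure D2:**
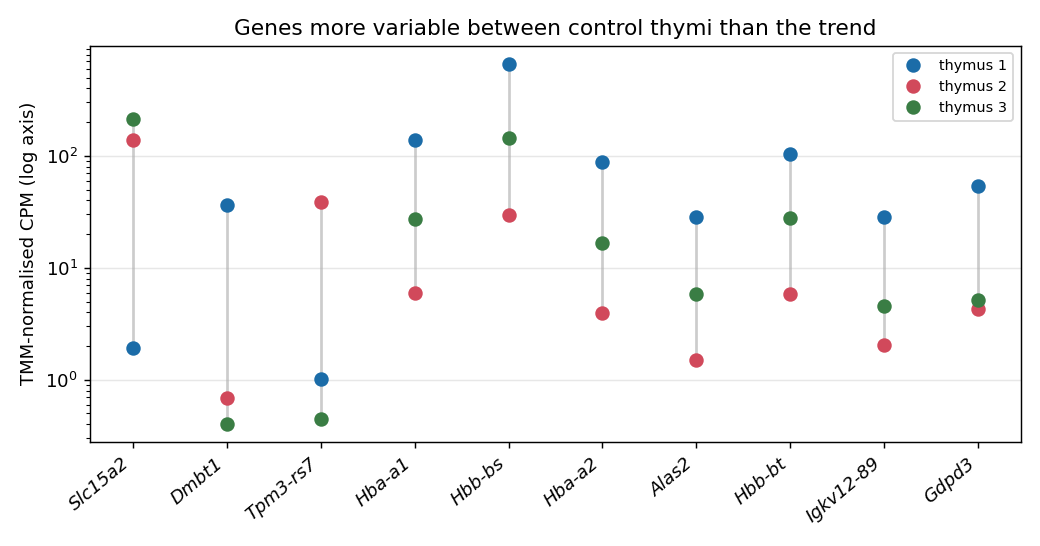
Genes more variable between control thymi than the trend for their abundance. The vertical log axis gives TMM-normalised CPM, each point is 1 thymus, and a line joins the 3 values of a gene. The globin genes and Alas2 are highest in thymus 1 and lowest in thymus 2, and Slc15a2 is at 1.91 CPM in thymus 1 against 139.6 and 213 CPM.

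Gene lists also showed differences between thymi. Each list's median was set against 10000 random lists matched on expression, as a description of these 3 libraries. The pair of thymus 3 and thymus 2 was chosen for the following values after their low correlation was seen. Heat shock genes were higher in thymus 3 than in thymus 2 by a median log2 difference of 0.70 (percentile 100), and 8 of 10 had the order thymus 3, 1, 2. Hsp90aa1 was at 656, 218 and 411 CPM in that pair and in thymus 1, Hsph1 at 309, 107 and 210.5, and Hspa8 at 983, 641 and 857. Over all genes edgeR called 0 of the 10, the DESeq2 dispersion check 3 and the negative binomial goodness of fit 4, and edgeR called 7 when adjusted over the list alone. Of Hsp90aa1, 47.5% of the 50-base stretches occur in other transcripts.

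Cell cycle genes were higher in thymus 3 than in thymus 2 by a median log2 of 0.26, with 12 of 15 highest in thymus 3, Pcna among them at 504 CPM against 335. Mature single-positive genes were lower in thymus 3, at −0.36, and so were early progenitor genes at −0.35, macrophage and dendritic cell genes at −0.32 and B cell genes at −0.30. All 13 macrophage and dendritic cell genes were lowest in thymus 3. Neutrophil genes were higher in thymus 3 by 1.37, with S100a9 at 18.3 CPM against 6.24 and S100a8 at 15.1 against 6.58. Fat genes were lower in thymus 3 than in thymus 2, at −0.57. The 7 mitochondrially encoded genes tested were all highest in thymus 3 and lowest in thymus 2, with a median log2 difference of 0.63. Mt-Cytb was at 7322 CPM in thymus 3 and 4551 in thymus 2. Replication-dependent histone genes were higher in thymus 3 by 0.57 (percentile 99.9), and all 5 tested were highest there. That list was low, with medians of 0.592, 0.597 and 1.16 CPM in thymus 1, 2 and 3. Of its 8 genes 3 were below 1 CPM in every library. Thymic epithelial genes, at −0.16, and the Notch and leukaemia genes, at −0.25, lay below the range of random lists. Both lay inside it with correction for GC content, at −0.08 and −0.14, and below it with correction for GC content and exon length, at −0.09 and −0.17. Double-positive genes (−0.01) and interferon-stimulated genes lay inside the range in this pair. Against the mean of the 3 thymi, double-positive genes were higher in thymus 2, at 0.03 (percentile 98.2), but inside the range with either correction. Interferon-stimulated genes were higher than that mean in thymus 1, at 0.17 (percentile 100), with 10 of 12 highest there. In thymus 2 they were lower, at −0.10 (percentile 0.45).

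Capicua target genes differed by −0.15 (percentile 11.2), and by −0.21 (percentile 1.70) after correction for GC content. Against the mean of all 3 thymi they were lower in thymus 3 by a median log2 of −0.14 (percentile 1.31), and 10 of the 13 tested were lowest there. With a joint correction for GC content and exon length both values lay inside the range of random lists, at −0.19 (percentile 3.26) and −0.09 (percentile 4.88).

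The libraries also differed in a trend with the GC content of transcripts, and all list differences above stand beside it. The Spearman correlation across 16522 genes between GC content and the deviation from the gene mean was −0.165 in thymus 1, 0.416 in thymus 2 and −0.290 in thymus 3. With exon length in place of GC content it was 0.135, 0.0586 and −0.124. After removal of the GC trend the mitochondrial difference was 0.30, down from 0.63, and that of heat shock genes was 0.72. In all, 42 of 87 values of a list in a library lay outside the central 95% of random lists, where 4.35 would by chance if genes varied independently. Of the 29 lists, 14 lay above the central 95% of random lists in their variability between thymi.

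Called by gene (edgeR quasi-likelihood, Benjamini-Hochberg 0.05), the erythroid list had 5 of 6 tested genes over all genes, and 5 adjusted over the list alone. The other 28 lists had 0 of 260 genes over all genes, with 51 at an unadjusted p under 0.05, 16 by negative binomial goodness of fit and 11 by DESeq2 dispersion outliers. Adjusted over the list alone, 8 of these lists had calls: heat shock 7, neutrophils 5, adipocytes 5, sex-linked 3, and 1 each for B cells (Jchain), macrophages and dendritic cells (Ccl22), parathyroid (Pth) and mitochondrial genes (mt-Nd6). With GC correction the variability of the sex-linked list moved from percentile 100 to 77.6 of random lists, and the mitochondrial from 99.98 to 97.1. Heat shock, neutrophil and adipocyte lists stayed at percentile 100. The remaining 20 lists had 0 of 193 adjusted over the list alone, with 18 at an unadjusted p under 0.05, 1 by goodness of fit and 0 by DESeq2. They include the glucocorticoid-responsive genes, led by Txnip (609 ± 29.5 CPM) and Fkbp5 (296 ± 16.2), the estrogen-responsive and tamoxifen-related genes, led by Tiparp (76.8 ± 7.85), the immediate early genes, led by Egr1 (89.7 ± 6.71), the clock genes, led by Arntl (105 ± 2.87), and the histone genes, led by Hist1h2bc (29.7 ± 5.30). Against the gene mean, the estrogen-responsive and tamoxifen-related list was at 0.10 (percentile 98.95) in thymus 1 and −0.15 (percentile 0.95) in thymus 2. Both values lay inside the range of random lists with correction for GC content and exon length, at percentiles 97.47 and 4.37. The glucocorticoid-responsive list was lower in thymus 1, at −0.06 (percentile 0.47), and stayed outside that range with either correction.

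**Figure D3:**
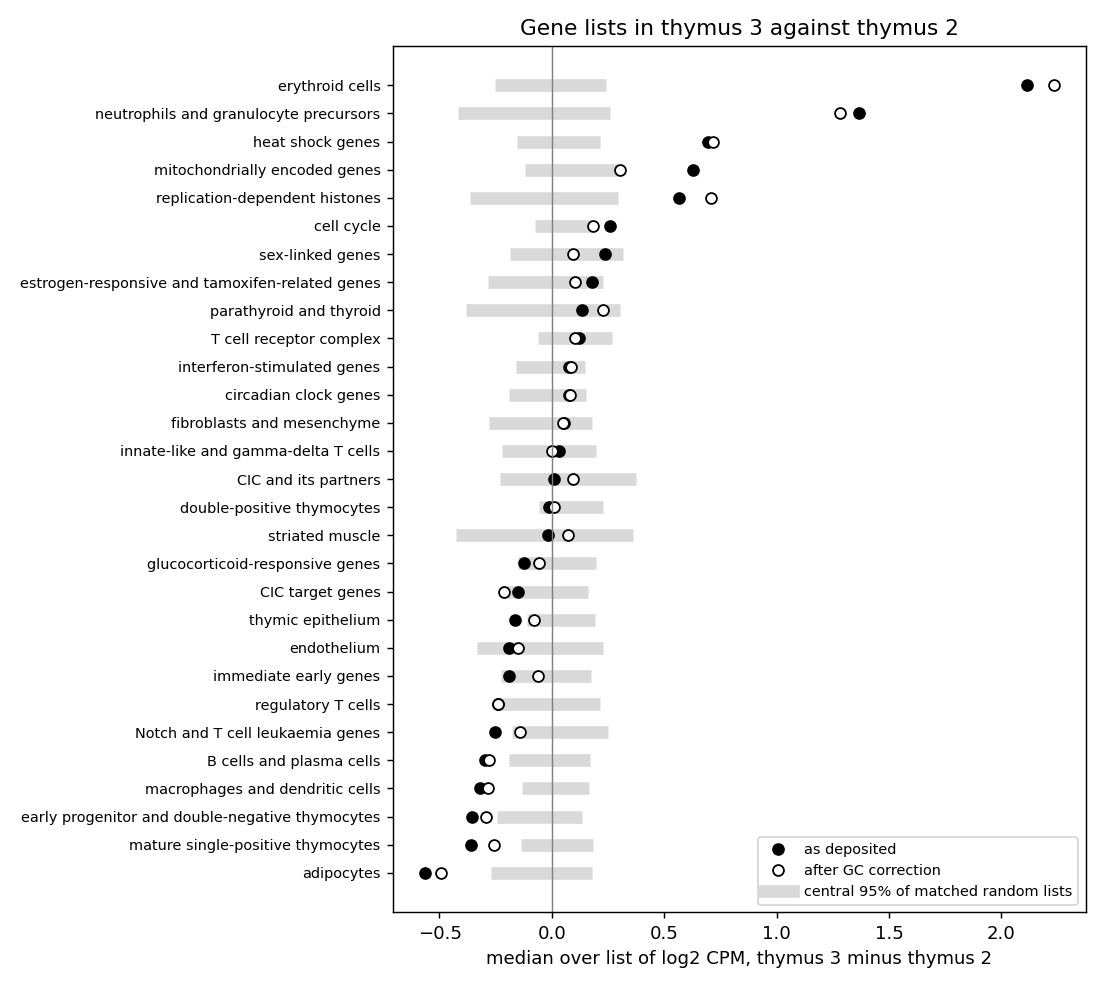
Gene lists in thymus 3 against thymus 2. The horizontal axis gives the median over each list of log2 CPM in thymus 3 minus thymus 2, filled points as deposited and open points after the trend with GC content was removed, and grey bars hold the central 95% of matched random lists. Heat shock genes stay near 0.70 on both scales, while mitochondrially encoded genes move from 0.63 to 0.30.

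Reads fell on the strand that the stranded library kit predicts. Of the gene counts summed over both strand columns, 96.6% ± 0.0361 (SD, n = 3) lay on the strand of the gene's own transcript. The exact 95% binomial interval was 96.6213% to 96.6339% in thymus 1. A read over genes on both strands can enter both columns, so these are shares of counts, not of separate reads. The interval treats the counts as separate reads. Counts on the opposite strand made up 3.41% ± 0.0361 of that sum. Among 9836 genes at 10 CPM or more the median opposite-strand share was 0.165%. Genes with a mean of at least 1 CPM on the opposite strand and more reads there than on their own in every library numbered 1563. They held 65.7% of all opposite-strand reads. Of those genes, 1448 overlap an expressed gene on the other strand, as Tlcd1 does Rpl23a and Phykpl does Hnrnpab.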

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

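The strand count was planned, while Mroh2a was singled out after its value was seen. Reads on the strand opposite to a gene are not part of that gene's level. Where another gene lies on that strand, the same reads can be counted in the level of that other gene. They drew attention where they reached a mean of 1 CPM, above the 3-count limit, and exceeded the gene's own reads. Of genes with a mean of at least 1 CPM on the opposite strand, 1563 had more opposite-strand than own-strand reads in every library. Of these, 108 overlap no expressed annotated gene on that strand. Another 7 have no position in the annotation used, so their overlap is not known.

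Among the highest mean opposite-strand levels (n = 3) were those of mt-Nd6 at 493 ± 44.9 CPM, which overlaps mt-Nd5 on the other strand by 14 bases, and of Gm20721 at 426 ± 42.1, which overlaps Gnas. CT010467.1, an annotated ribosomal RNA gene, had 395 ± 22.4 CPM opposite to its strand, where Gm42418 lies. Gm16042, a processed pseudogene, had 267 ± 8.03 inside Glcci1, whose own level was 62.5 ± 6.20. Tlcd1 had 263 ± 43.4 CPM against Rpl23a at 262 ± 43.98. Phykpl had 224 ± 18.3 against Hnrnpab at 537 ± 22.9. Mroh2a (chromosome 1, 88226986 to 88262289, plus strand) had the highest level among genes with a symbol and no expressed annotated partner, 53.0 ± 3.68 CPM on the minus strand against 0.718 ± 0.238 on its own. No explanation was tested for these signals.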

How the results depend on the processing

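The corrections for GC content and exon length and the levels per kilobase were chosen after seeing the data. No paired analysis was possible because the samples form 1 group. No result changed direction past its threshold. The double-positive over T cell receptor median, which has no threshold, was 1.45 in CPM and 0.485 per kilobase of exon, so the order reversed. The count of genes more variable than the trend, 10, depended most on the setting: 20 with library totals, 285 with no filter, where 30857 genes were tested, 19 with GC and exon length correction, 122 by negative binomial goodness of fit, 81 by DESeq2 dispersion outliers and 23 to 137 with 1 library left out. All 10 genes were among those called in the first 5 of these, and the cause of the higher counts was not tested beyond the number of genes. With 1 library left out, 3768 to 6579 genes varied beyond counting noise, and the biological coefficient of variation was 9.39% to 13.04%. Per kilobase of exon the double-positive median was 54.8 times the early progenitor median, 13.3 times the mature single-positive, 89.8 times the capicua target, 5.45 times the thymic epithelial, 28.8 times the B cell, 6.06 times the macrophage and dendritic cell and 245 times the leukaemia gene median, where exon length is the only change. Among genes past the filter the own-strand share was 97.7%. Of 130 repeats of the calls of the 10 named variable genes 12 were lost: 6 with 1 library left out, and 6 of Alas2 or Igkv12-89 under another column, scaling, filter or prior. Of 976 repeats of a named gene's mean level 36 moved by more than 1 SD, and 139 of the repeats of 16 list differences between thymus 3 and thymus 2 kept their side of the range of random lists. The 3 that did not came with GC correction: capicua targets left the range (−0.21), and thymic epithelium (−0.08) and leukaemia genes (−0.14) entered it. Capicua targets in thymus 3 against the gene mean entered it with no filter (−0.12) and with GC and exon length correction (−0.09), and double-positive genes in thymus 2 with either correction. List deviations were not run with 1 library left out, since deviations of 2 libraries mirror each other. Depth limits genes near 0.0986 to 0.122 CPM, the level of 3 counts.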

Other observations

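The tests of neutrophil genes, of the ratio of erythroid transcripts, of gene positions with their repeats and of Tpm3-rs7, and all values of antigen receptor V genes, were chosen after the result was seen; the GC corrections were chosen after the GC trend was seen and before any corrected value. Immunoglobulin V genes were expressed unevenly between thymi. Their summed level was 638, 542 and 659.7 CPM in thymus 1, 2 and 3, but single genes had a median coefficient of variation of 44.8% (121 genes tested). Over all genes edgeR called 1 of the 121 more variable than the trend. Of the 100 genes with the largest range among those with a mean of at least 1 CPM, 49 were immunoglobulin V genes. T cell receptor beta V genes had a median coefficient of variation of 15.6% (24 genes) and alpha V genes 17.6% (46 genes), and 0 of either were among those 100. The median spread over trend was 9.02 for immunoglobulin V genes, 3.72 for beta V genes and 0.734 for alpha V genes, at percentiles 100, 100 and 22.2 of matched random lists.

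Lep, the leptin gene of white fat, was at 5.42, 22.1 and 10.2 CPM in thymus 1, 2 and 3. Ucp1, the thermogenic uncoupling protein of brown fat, was at 0.789, 3.48 and 15.3 CPM (edgeR quasi-likelihood, adjusted p = 0.0716). Both are adipocyte list members chosen here after their values were seen. Among macrophage genes chosen the same way, Cd209b was at 12.2, 1.16 and 0.527 CPM (edgeR adjusted p = 0.0594) and Timd4 at 17.9, 8.18 and 5.27 CPM (edgeR adjusted p = 0.425), and neither passed the threshold over all genes.

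The globin genes and Alas2 were highest in thymus 1, by a median log2 of 4.46 over thymus 2. The GC trend does not account for this, since the difference was 4.52 after its removal. Of the 8 neutrophil genes tested 6 were lower in thymus 1 than in thymus 3, with a median log2 difference of −1.11 (percentile 0 of random lists). This argues against whole blood as the only source of both globin and neutrophil transcripts in these thymi. The neutrophil order was known beforehand, and list medians were low, at 0.986, 1.02 and 2.72 CPM in thymus 1, 2 and 3. Against the gene mean the list was at −0.23 in thymus 1 and −0.48 in thymus 2, the order of the globin genes. Blood as a source of globin alone was not tested. The thymus 1 over thymus 2 folds of alpha globin, Hbb-bs, Hbb-bt and Alas2 lay between 17.9 and 22.9. The largest was 1.28 times the smallest. Since similar folds had been seen before, this ratio describes them and is no independent test. It would be seen if 1 kind of erythroid RNA, present in different amounts, were the source of these transcripts. Gata1, the other erythroid gene tested and named here after its values were seen, did not follow them, at 0.723, 1.33 and 1.01 CPM in thymus 1, 2 and 3, and the remaining 3 of the list lay below 1 CPM. Whether the globin and Alas2 RNA came from red cells left in vessels or from erythroid cells in the tissue stays open. The design names no biological difference between these mice to test.

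The list differences between thymus 3 and thymus 2 were weighed against the GC trend. After its removal the median log2 difference was 0.72 for heat shock genes, 0.18 for cell cycle genes, −0.26 for mature single-positive genes and −0.29 for early progenitor genes, each still outside the central 95% of random lists corrected the same way, which argues against the trend as the whole cause. For mitochondrially encoded genes it was 0.30, against 0.63 before, and lay at percentile 99.7, so the trend and a difference in mitochondrial RNA cannot be told apart: the value dropped by more than 50% but stayed outside the range of random lists. Handling before lysis, RNA quality, animal age and the share of each cell type could also differ between the thymi and were not tested. The same holds for library preparation, including the selection of polyadenylated RNA.

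Slc15a2, Dmbt1, Gdpd3 and Tpm3-rs7 each stood apart in 1 thymus. Segments of another strain's genome may cause this, and would place such genes close together. Gdpd3 and Dmbt1, both high in thymus 1, lie 4.27 Mb apart on chromosome 7, and were left out of the test because they prompted it. Among the 50 genes with the largest range, leaving out these 2, globin and antigen receptor genes, 7 pairs lay within 10 Mb with the same outlying thymus, against a median of 4 and a 95th percentile of 8 in 10000 random draws. Of these, 3 pairs are neutrophil genes of chromosome 9, and 4 remain without that list, while the 50 highest-ranging genes outside every list gave 9 pairs against a 95th percentile of 8, so the test decides nothing. For Tpm3-rs7, counts were 26.3% of those of Tpm3 in thymus 2 and at most 0.594% in the others, a ratio of 44.2. Reads of Tpm3 assigned to it at 1 constant rate would not give this. The gene was picked for its high level in thymus 2, so the ratio is no independent test. It leaves open whether Tpm3 reads were assigned to Tpm3-rs7 in thymus 2 alone.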
